A study of Mus musculus with 6 samples.

How the data were processed

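The samples were pools of gonadal primordium epithelium from mouse fetuses at embryonic day 10.5, 3 wild-type and 3 Emx2 KO, with material of 3 fetuses in each. Per the labels' protocols, unfixed frozen fetuses were sectioned at 30 µm and stained with hematoxylin, GATA4 immunostaining of some sections served to find the primordium, its epithelium was taken by laser microdissection, and 15 ng of total RNA per pool went through 2 rounds of amplification and biotin labelling. The labels do not say whether fetuses of different pools shared a litter, and p-values measure the spread between pools.

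The values used are the intensities the authors deposited, 1 linear number per probe set and array for 45101 probe sets on 6 1-channel arrays. GCOS 1.2 is named in the submitters' processing notes. Which algorithm, scaling target or filter was used in it is not given in the sources used here. The deposited median intensities were 40.6, 47.0 and 63.6 in the wild-type arrays and 59.8, 54.2 and 48.2 in the KO arrays. The arrays were not at a common level: their 2% trimmed means were 254, 284 and 373 in wild-type and 356, 317 and 289 in KO arrays, the highest being 1.47 times the lowest. Differences of up to 5% had been set as the limit for using the values unscaled.

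Each array was therefore scaled to a common 2% trimmed mean of 309.2. Values below the 20th percentile of all scaled values (7.99) were set to it, and log2 was taken. The 64 control probe sets and the 40% of probe sets with the lowest mean log2 value over all 6 arrays (below 4.72, an intensity of 26.4) were left out, and 27022 were tested. Amplification over 2 rounds shortens the copied RNA, so probe sets far from the 3' end can read low, and a fold is compressed where a group lies near the floor. No detection calls were used. A group mean under 26.4 is described as under the dim limit, and where all values of a group lay at the floor the difference is given as a lower bound.

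Probe sets were named from the platform's annotation table, in which 34958 had 1 gene symbol, 932 several and 9211 none. Of those with 1 symbol, 34754 matched a gene of the RefSeq table of assembly GRCm38.p6 by gene identifier, and 0 symbols changed. Only names and the order of neighbouring genes were taken from that table, since the genome build behind the array annotation is not given in the sources used here. Probe sets with several symbols or none were tested but not named. The tested probe sets covered 12315 genes, 5737 of them through more than 1 probe set.

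KO and wild-type pools were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The prior had 8.74 degrees of freedom. Adjusted p-values of genes come from this test, means and SDs are of scaled intensities, and log2 fold changes are KO minus wild-type with their SE. The median log2 fold change of all tested probe sets was 0.01.

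Gene lists for gonadal regulators, epithelial organisation, signalling pathways, metabolism and the cell types that microdissected tissue could hold were fixed before the data were examined. The probe set with the highest mean log2 value stood for each gene. Lists with at least 5 measured members were tested against all other genes with camera (limma), with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the 34 lists. A list with fewer members, the markers of female and male fetuses, was described gene by gene.

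The genes named were set by a rule fixed beforehand. It took every Emx2 probe set; the 12 rises and 12 falls of greatest size among called probe sets with 1 symbol and non-overlapping groups, 1 probe set per gene, that of smallest p; up to 4 called members of each list by size of change, filled to 2 by p where fewer were called; and Egfr, Nr5a1, Gata4, Wt1, Lhx9 and Tjp1. Some further called members of a list are named where its count is given, and Emx2os, Afp and the genes described only in the closing section were chosen after their values were seen. For control genes, ratios of 3' to 5' probe sets were compared with exact permutation tests.

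The alternatives were quantile normalization, scaling to a common median, a floor at the 40th percentile, a pseudocount in place of the floor, no floor, no filter, a filter of the lowest 60%, the replicate number as a block, array weights, no intensity trend, an adjusted p threshold of 0.1, probe sets open to cross-hybridisation left out, the mean of all probe sets of a gene, fewer lists, and each pool left out in turn. Values as deposited without rescaling, no filter together with no floor, and X- and Y-linked genes left out were added after seeing the data.

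The procedure was tested on simulated arrays in which 98 of the 27022 tested probe sets changed by 2-fold and 98 by 4-fold. It called 150, recovered 58 of the 2-fold changes (59.2%) and 87 of the 4-fold changes (88.8%), and called 5 unchanged probe sets. In simulated arrays without change, camera called 0 of 34 lists, and a list shifted by 0.5 on the log2 scale was found. Simulated probe sets were drawn independently of each other, whereas in the real arrays the estimated correlation was 0.45 within ribosomal protein genes. The simulation therefore does not show how often camera calls lists of correlated genes by chance. The number of arrays limits the precision of every value.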

Results

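Gene expression was measured in the epithelium of the mouse gonadal primordium, the thickened coelomic lining of the urogenital ridge from which the gonad forms, at E10.5 of development. The cells were cut out by laser microdissection from wild-type fetuses and from fetuses lacking Emx2, a homeobox gene required for development of the urogenital system. Material from 3 fetuses made up each pool, and 3 wild-type and 3 Emx2 knockout (KO) pools were each hybridised to an array of 45101 probe sets. The comparison asked which genes differ in this epithelium when Emx2 is missing. Across probe sets, which are not independent replicates, log2 intensities correlated with r between 0.977 and 0.983 for the 6 pairs of arrays within a group and between 0.964 and 0.972 for the 9 pairs across groups. With 3 arrays per group, the median standard error (SE) of a log2 fold change was 0.188.

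The only probe set of Emx2 itself did not pass the test. Its scaled intensity was 1302, 2120 and 1727 in the wild-type pools and 1678, 1480 and 1746 in the KO pools. The means were 1716 ± 409 and 1634 ± 138 (SD, n = 3 each; log2 fold change −0.05, SE 0.15, adjusted p = 0.916). Where this probe set lies relative to the part of the gene removed in the mutant is not given in the sources used here. Its signal therefore does not check the group labels, and KO below means the pools labelled so. Emx2os, the transcript named for the opposite strand at the Emx2 locus and chosen after its values were seen, fell from 190 ± 34.7 to 38.8 ± 8.88 (log2 fold change −2.30, SE 0.24, adjusted p = 0.00015). Its pools read 167, 230 and 174 in wild-type against 44.9, 28.6 and 42.9 in KO.

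Markers of the sex of the pooled fetuses separated the same pools as the genotype did. Xist, the RNA that coats the inactive X chromosome of female cells, rose from 34.6 ± 30.8 to 9512 ± 326 (SD, n = 3 each; log2 fold change 8.47, SE 0.42, adjusted p = 4.16e-07). A further Xist probe set lay at the intensity floor in all wild-type pools and between 7209 and 8363 in the KO pools, a difference of at least 9.89 on the log2 scale (adjusted p = 3.54e-13). All 3 Y-linked genes tested fell. Eif2s3y went from 776 ± 58.5 to 160 ± 63.2 (−2.35, SE 0.23, adjusted p = 9.67e-05) and Kdm5d from 357 ± 60.4 to 79.3 ± 24.0 (−2.20, SE 0.23, adjusted p = 0.000123). A dimmer Kdm5d probe set fell less, reading 31.5, 35.1 and 51.3 in the wild-type pools and 25.6, 30.4 and 23.4 in the KO pools. Uty went from 233 ± 27.1 to 53 ± 4.95 (−2.13, SE 0.19, adjusted p = 6.07e-05), and its other tested probe sets gave −2.61 and −3.03. These calls did not depend on the size of the list: adjusted over the list alone, 1 gene was higher and 3 were lower, as over all probe sets. The labels do not give the sex of the fetuses, and every difference below was measured between pools that also differed in these genes. Genes named below are not marked by chromosome, and X-linked ones among them may differ with the sex of the pools.

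**Figure D1:**
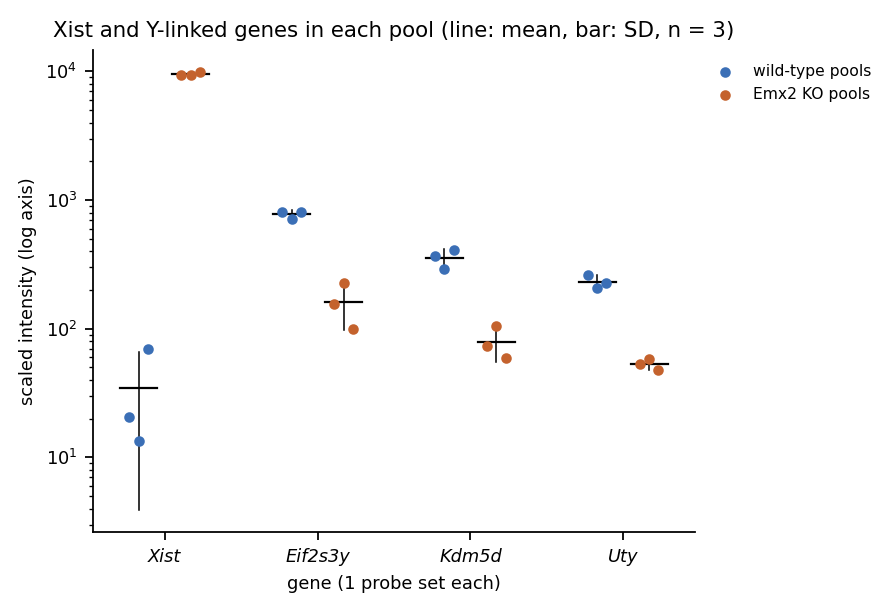
Scaled intensity (log axis) of Xist and 3 Y-linked genes in each wild-type (blue) and Emx2 KO (orange) pool, with horizontal lines for means and vertical bars for SD, n = 3 each. Xist averaged 34.6 in wild-type and 9512 in KO pools, while Eif2s3y, Kdm5d and Uty were lower in every KO pool than in any wild-type pool.

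Several developmental regulators and signalling genes differed strongly between KO and wild-type epithelium. Tbx18, a T-box transcription factor of the coelomic lining and of ureteric mesenchyme, rose from 518 ± 156 to 4897 ± 374 (SD, n = 3 each; log2 fold change 3.29, SE 0.18, adjusted p = 9.95e-07). Egfr, the receptor for epidermal growth factor, rose from 38.0 ± 11.2 to 746 ± 141 (4.32, SE 0.23, adjusted p = 6.22e-07). Cbln1, a secreted protein best known as an organiser of synapses, fell from 1398 ± 545 to 65.3 ± 31.2 (−4.45, SE 0.32, adjusted p = 1.06e-05). Inhbb, a subunit of activin and inhibin, fell from 480 ± 142 to 35.0 ± 15.3 (−3.85, SE 0.34, adjusted p = 4.9e-05). Egfr was among the genes named beforehand because the study's authors reported on it elsewhere from the same mutants, so its rise is not independent evidence.

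In limma's test, 1264 of 27022 probe sets passed the threshold, 742 of them higher and 522 lower in the KO pools. They named 427 genes that rose and 372 that fell. Among them 311 probe sets were higher and 247 lower by at least 2-fold. An unadjusted p under 0.01 together with a change of at least 2-fold was met by 666 probe sets, 373 higher and 293 lower. An unadjusted p under 0.01 alone was met by 2219, where chance would give 270. The 3 values of each group did not overlap in 5934 probe sets (22% of those tested, where chance gives 10%), and in 1262 of those called. The count of called probe sets depended on single pools, being 721 without wild-type replicate 1, 815, 834 and 790 without KO replicates 1, 2 and 3 in turn. The higher count was 450 without wild-type replicate 1 and 441, 468 and 452 without the KO replicates in turn. The lower count was 271 without wild-type replicate 1, 795 without wild-type replicate 3 and 338 without KO replicate 3. The total was 151 when no dim probe sets were left out.

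Among the 12 genes with the greatest rises that passed, each taken by its probe set of smallest p, Xist and Egfr were followed by Irs4, an adaptor of insulin signalling, which went from 30.3 ± 18.5 to 347 ± 15.5 (log2 fold change 3.69, SE 0.34, adjusted p = 6.07e-05). After Tbx18 came Tmem255a (268 ± 68.5 to 2190 ± 659, log2 fold change 3.02, SE 0.21). Col25a1, a transmembrane collagen, rose too (50.0 ± 19.4 to 308 ± 53.9, log2 fold change 2.70, SE 0.29). Also higher were Apela, a peptide ligand of the apelin receptor (60.2 ± 19.9 to 385 ± 116; 2.70, SE 0.28), and the membrane glycoprotein Gpm6a (90.2 ± 30.2 to 507 ± 81.1; 2.54, SE 0.24). A second Col25a1 probe set did not pass (0.96, adjusted p = 0.23). Fut9, a fucosyltransferase (log2 fold change 2.81, SE 0.35), Ntng2, a netrin-related cell surface protein (2.70, SE 0.36), Slitrk6, a neuronal membrane protein (2.54, SE 0.40), and the kinase gene Stk17b (2.24, SE 0.49) completed this set. Their wild-type signals of 10.7 ± 6.45, 11.7 ± 7.39, 22.4 ± 9.35 and 13.2 ± 11.4 lay under the dim limit of 26.4, and Stk17b passed in only 2 of the 4 fits with 1 pool left out in which it was tested. With the floor at the 40th percentile the log2 fold changes of Fut9, Ntng2 and Stk17b were 1.48, 1.55 and 1.12, and Stk17b did not pass, so the size and rank of these rises depend on the floor. Both other tested Stk17b probe sets were brighter and did not pass, at 212 ± 19.2 and 241 ± 9.7 (0.19, SE 0.15, adjusted p = 0.588) and at 284 ± 43.6 and 322 ± 55.5 (0.18, SE 0.17, adjusted p = 0.667).

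The 12 genes with the greatest falls that passed, each taken by its probe set of smallest p, began with Cbln1 and Inhbb. Of Uty, that probe set (−2.13) fell less than these. Dct, an enzyme of melanin synthesis, fell from 266 ± 44.4 to 23.8 ± 17.2 (log2 fold change −3.76, SE 0.45, adjusted p = 0.000358), and Cfap161, a cilium-associated gene, from 190 ± 49.7 to 16.7 ± 3.94 (−3.51, SE 0.28, adjusted p = 2.23e-05). The sarcomere genes Mybpc1 (188 ± 52.2 to 18.5 ± 5.93; −3.36, SE 0.32) and Myh6 (219 ± 42.4 to 39.3 ± 6.96; −2.47, SE 0.23) fell as well. So did Adtrp (−2.98, SE 0.39), the aminopeptidase gene Enpep (−2.95, SE 0.41) and the nuclear receptor gene Nr0b1 (−2.90, SE 0.34). The last were the transcription factor gene Sp6 (183 ± 7.83 to 27.8 ± 6.90; −2.75, SE 0.24), Gpat3, an enzyme of glycerolipid synthesis (−2.54, SE 0.48), and the protease gene Adamts18 (−2.47, SE 0.47). A second Inhbb probe set did not pass (−1.49, adjusted p = 0.129), nor did a second, dimmer Sp6 probe set (31.6 ± 5.86 and 28.6 ± 7.31; −0.16, adjusted p = 0.863). Adamts18 no longer passed without wild-type replicate 1, where its log2 fold change was −2.12. The KO means of Dct, Cfap161, Mybpc1, Adtrp, Nr0b1, Gpat3 and Adamts18 lay under the dim limit, so their folds are less certain than their direction. With the floor at the 40th percentile Gpat3 gave −1.30, and Gpat3 and Adamts18 did not pass without an intensity trend (adjusted p = 0.0665 and 0.0785).

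**Figure D2:**
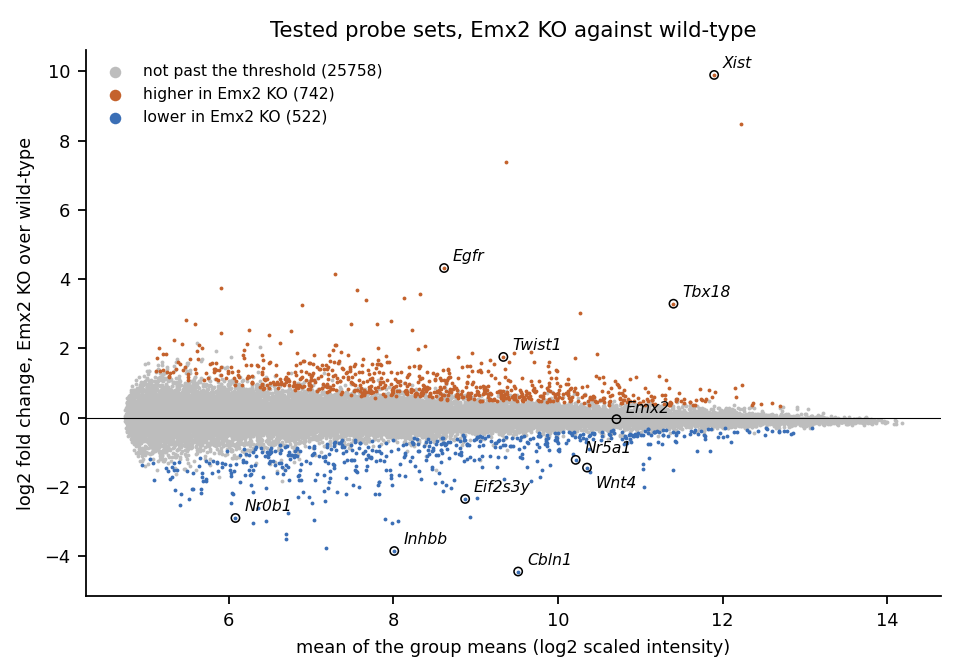
Log2 fold change of Emx2 KO over wild-type against mean intensity (log2) for the 27022 tested probe sets, with 742 called higher in orange, 522 called lower in blue and the rest in grey. Circled probe sets carry their gene names; Egfr (4.32), Tbx18 (3.29), Inhbb (−3.85) and Cbln1 (−4.45) stand outside the grey band, whereas Emx2 (−0.05) lies in it.

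Regulators of the gonadal primordium moved in opposite directions. Nr5a1, the orphan nuclear receptor on which gonad and adrenal formation depends, fell from 1666 ± 345 to 710 ± 102 (SD, n = 3 each; log2 fold change −1.22, SE 0.15, adjusted p = 0.000492). Wnt4, a signal required for ovary and kidney development, fell from 1911 ± 362 to 703 ± 144 (−1.44, SE 0.16, adjusted p = 0.000218). Nr0b1, a repressor of Nr5a1 activity, fell from 119 ± 27.9 to 16.5 ± 6.96 (adjusted p = 0.000303) and Dmrt1 from 109 ± 54.1 to 22.5 ± 4.24 (−2.18, SE 0.34, adjusted p = 0.00256), the KO means of both lying under the dim limit. Osr1, a regulator of intermediate mesoderm, rose from 136 ± 23.9 to 334 ± 82.4 (1.29, SE 0.21, adjusted p = 0.00295). Of the 22 measured genes of this list, 3 rose (Osr1, Tcf21 and Nr2f2), 5 fell (Rspo1 being the fifth) and 14 did not pass. The counts were 8 higher and 8 lower adjusted over the list alone. Lhx9 gave 6156 ± 498 and 6262 ± 553 (0.02, SE 0.09, adjusted p = 0.926), its sign turning under another scaling. Wt1 gave 2620 ± 136 and 2002 ± 308 (−0.40, SE 0.11, adjusted p = 0.0715). Gata4, whose protein was stained to find the primordium on some sections and which is therefore no finding here, gave 276 ± 60.7 and 418 ± 10.8 (0.62, SE 0.16, adjusted p = 0.0501). Tested against all other genes with camera, the list did not pass (adjusted p = 0.939). Among 9 measured genes of the adrenocortical primordium, which shares Nr5a1 and Nr0b1 with the gonad, 2 rose and 3 fell, against 3 and 6 adjusted over the list alone (camera adjusted p = 0.0632). Fdx1, which carries electrons to steroidogenic enzymes, fell by 0.61 (SE 0.11, adjusted p = 0.00499). Mc2r, the receptor for adrenocorticotropic hormone, rose from 516 ± 77.6 to 821 ± 31.2 (0.68, SE 0.13, adjusted p = 0.0106).

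**Figure D3:**
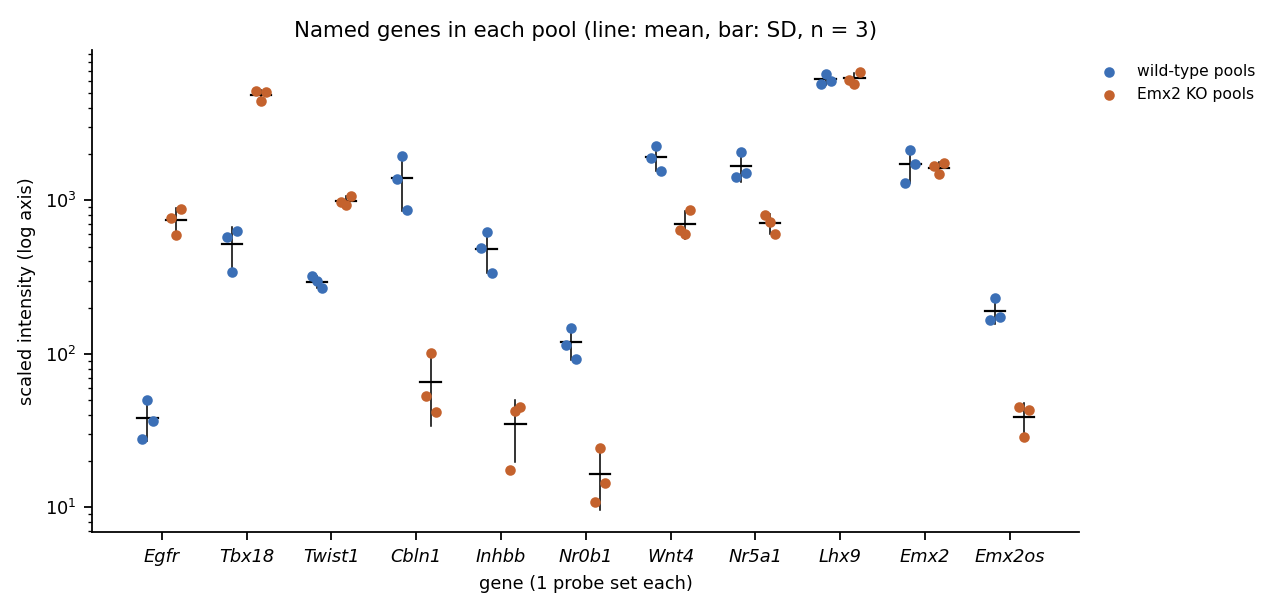
Scaled intensity (log axis) of 11 genes, 1 probe set each, in the wild-type (blue) and Emx2 KO (orange) pools, with horizontal lines for means and vertical bars for SD, n = 3 each. Egfr, Tbx18 and Twist1 were higher and Cbln1, Inhbb, Nr0b1, Wnt4, Nr5a1 and Emx2os lower in all KO pools, whereas the pools overlapped for Lhx9 and Emx2.

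Markers of the coelomic epithelium and mesothelium went both ways. Of 19 measured, 6 rose (Tbx18, Gpm6a, Upk1b, Lrrn4, Krt19 and Bnc1), 3 fell (Aldh1a1, Krt8 and Rspo1) and 10 did not pass. The counts were 7 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0632). Upk1b, a uroplakin of mesothelial surfaces, rose from 171 ± 5.29 to 466 ± 63.7 (log2 fold change 1.44, SE 0.15, adjusted p = 0.00015). Krt8, a keratin of simple epithelia, fell from 2184 ± 222 to 1452 ± 104 (−0.59, SE 0.11, adjusted p = 0.00615). Aldh1a1, an enzyme that makes retinoic acid, fell from 1226 ± 502 to 489 ± 98.5 (−1.26, SE 0.25, adjusted p = 0.0112), a call that was lost without wild-type replicate 1 (log2 fold change −1.21).

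Tjp1, which encodes the tight junction protein ZO-1 and was named beforehand for the same reason as Egfr, gave 2323 ± 302 in wild-type and 2628 ± 178 in KO pools (log2 fold change 0.18, SE 0.11, adjusted p = 0.417). Of 15 tight junction genes, 2 rose (Cgnl1, 0.58, SE 0.13, and Cldn5, 0.85, SE 0.22) and 0 fell, also adjusted over the list alone (camera adjusted p = 0.359). Cldn5 also stands in the endothelium list given below. Of 25 genes of apicobasal polarity complexes, each read by its brightest probe set, Ezr alone rose, from 1235 ± 96.2 to 1768 ± 225 (0.51, SE 0.12, adjusted p = 0.022), against 4 higher adjusted over the list alone. At its brightest probe set Mark1, next by p, gave 0.52 (SE 0.14, adjusted p = 0.0634), and other Mark1 probe sets are not given here. Camera's adjusted p for the list was 0.103. Among 20 genes of adherens junctions and desmosomes 2 rose and 1 fell, against 4 and 1 adjusted over the list alone (camera adjusted p = 0.461). Cdh11, a cadherin typical of mesenchyme, rose from 414 ± 36.2 to 832 ± 107 (1.00, SE 0.14, adjusted p = 0.000846). Nectin3 rose by 0.38 (SE 0.10) and Pkp2, a desmosomal plakophilin, fell from 1120 ± 42.8 to 578 ± 52.3 (−0.96, SE 0.12, adjusted p = 0.000393). With each pool left out in turn, Ezr, Cgnl1, Cldn5 and Nectin3 passed in 3, 2, 2 and 1 of the 6 fits, whereas Cdh11 and Pkp2 passed in all 6.

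Of 18 measured genes linked to epithelial-mesenchymal transition, 6 rose, 0 fell and 12 did not pass, against 8 higher and 0 lower adjusted over the list alone. Twist1, a transcription factor that represses epithelial genes, rose from 296 ± 27.2 to 996 ± 70.4 (SD, n = 3 each; log2 fold change 1.75, SE 0.13, adjusted p = 1.25e-05). Tgfb2, a growth factor of the TGF beta family, rose from 337 ± 80.2 to 1016 ± 93.1 (1.62, SE 0.17, adjusted p = 0.000153). Zeb2, a further repressor of epithelial genes, rose from 617 ± 89.8 to 1153 ± 144 (0.90, SE 0.14, adjusted p = 0.00195). Fn1, Prrx1 and Mmp14 also rose, Prrx1 by 0.81 (SE 0.20). Snai2 gave 4413 ± 428 and 5379 ± 319 (adjusted p = 0.0968) and Vim 3875 ± 140 and 4508 ± 324 (adjusted p = 0.187). The list passed camera with the preset correlation (adjusted p = 8.99e-07) but not with an estimated correlation (adjusted p = 0.13). The correlation estimated for it was −0.013, below the preset 0.01, so the loss did not come from a higher correlation between its genes. The same pools differed in Xist (log2 fold change 8.47) and, as given next, in markers of mesenchyme and endothelium.

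Of 18 measured markers of the urogenital ridge and lateral plate mesenchyme, a tissue directly under the epithelium, 7 rose, 1 fell and 10 did not pass. The counts were 11 higher and 2 lower adjusted over the list alone (camera adjusted p = 4.6e-05; adjusted p = 0.354 with an estimated correlation). Postn, a secreted matrix protein, rose from 1201 ± 266 to 2551 ± 290 (log2 fold change 1.10, SE 0.14, adjusted p = 0.000674). Pdgfrb, the receptor of perivascular and mesenchymal cells, rose from 667 ± 64.1 to 1200 ± 44.9 (0.85, SE 0.11, adjusted p = 0.000786). Twist1 and Prrx1 also stand in this list, and Tbx3 fell by 0.71 (SE 0.17, adjusted p = 0.0299). Among 29 genes of basement membrane and matrix 6 rose and 1 fell, against 7 and 6 adjusted over the list alone (camera adjusted p = 0.504). Lama2, a laminin chain, rose from 58.9 ± 6.74 to 183 ± 5.55 (1.64, SE 0.19, adjusted p = 0.000337). Fbln2 rose from 103 ± 13.8 to 231 ± 9.61 (1.17, SE 0.18) and Egfl6 from 33.2 ± 17.5 to 111 ± 38.2 (1.80, SE 0.37). Itga8, the integrin chain that binds nephronectin in the developing kidney, fell from 1331 ± 192 to 462 ± 62.2 (−1.52, SE 0.14, adjusted p = 6.95e-05). Egfl6 and Prrx1 passed in 3 and 1 of the 6 fits with 1 pool left out. The called members of the mesenchyme list, 8 in all, were 4, 4 and 5 without KO replicates 1, 2 and 3 in turn.

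Of 15 endothelial genes, 4 rose, 0 fell and 11 did not pass, against 8 and 1 adjusted over the list alone (camera adjusted p = 4.6e-05; adjusted p = 0.354 with an estimated correlation). Tek, the angiopoietin receptor, rose from 37.1 ± 5.34 to 90.2 ± 10.4 (log2 fold change 1.29, SE 0.24, adjusted p = 0.00834). Emcn rose from 22.0 ± 3.24 to 60.1 ± 23.0 (1.39, SE 0.33, adjusted p = 0.0306) and Egfl7 from 496 ± 60.9 to 703 ± 24.8 (0.51, SE 0.13, adjusted p = 0.0404). Cldn5, given above with the tight junction genes, also rose (0.85, SE 0.22). Of 7 genes of the nephric duct and mesonephric tubules, 0 rose, 3 fell and 4 did not pass, also adjusted over the list alone (camera adjusted p = 0.00481; adjusted p = 0.354 with an estimated correlation). They were Lhx1 (60.2 ± 15.2 to 20.7 ± 1.56; −1.51, SE 0.30, adjusted p = 0.0116) and Pax8 (92.2 ± 8.48 to 37.5 ± 13.2; −1.36, SE 0.29, adjusted p = 0.0166). The third was Bmp7 (146 ± 19.8 to 80.5 ± 14.6; −0.87, SE 0.21, adjusted p = 0.0324). Of 15 primordial germ cell genes, 0 rose, 3 fell and 12 did not pass, also adjusted over the list alone (camera adjusted p = 0.00181; adjusted p = 0.354 with an estimated correlation). Dppa5a fell from 1118 ± 203 to 621 ± 79.9 (−0.84, SE 0.15, adjusted p = 0.00588). Dppa3 fell from 242 ± 26.3 to 146 ± 28.9 (−0.74, SE 0.19, adjusted p = 0.0398) and Dnd1 from 95.1 ± 4.1 to 50.8 ± 8.11 (−0.92, SE 0.23, adjusted p = 0.0366). The wild-type mean of Emcn and the KO mean of Lhx1 lay under the dim limit. Dppa5a did not pass without an intensity trend (adjusted p = 0.0764) or on the deposited values (0.0678). Tek and Dppa5a passed in all 6 fits with 1 pool left out, Lhx1 in 5, Pax8 in 3, Emcn, Bmp7 and Dppa3 in 2, Egfl7 in 1 and Dnd1 in 0. Called endothelial members were 1 without KO replicate 1, 3 without wild-type replicate 2 and 2 without each other pool. Those of the nephric duct were 0 without wild-type replicate 1. Those of germ cells were 1 without wild-type replicates 1 or 2 and without KO replicates 1 or 3.

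Markers of other tissues near the gonad gave few calls. None of 11 erythroid genes passed (camera adjusted p = 0.612), and 1 was higher and 1 lower adjusted over the list alone. Tfrc lay at 2056 ± 502 and 1395 ± 128 (adjusted p = 0.0585) and the embryonic globin gene Hba-x at 7693 ± 660 and 9067 ± 344 (adjusted p = 0.11). None of 6 gut endoderm genes passed in either count (camera adjusted p = 0.558). Among them Ttr, with a KO mean under the dim limit, gave −1.72 (SE 0.67, adjusted p = 0.197) and Cldn6 −0.71 (SE 0.41, adjusted p = 0.428). None of 6 liver genes passed (camera adjusted p = 0.461), with Dlk1 at −0.45 (SE 0.13, adjusted p = 0.0651) and 1 lower adjusted over the list alone. Wild-type replicate 2 stood apart in liver genes. It had Ttr at 217 against 21.5 and 51.2 and Afp at 1668 against 43.5 and 392 in the other wild-type pools. Of 14 neural and neural crest genes, 2 rose and 1 fell, against 4 and 1 adjusted over the list alone (camera adjusted p = 0.359). The neurofilament gene Nefm rose from 38.1 ± 7.67 to 110 ± 22.9 (log2 fold change 1.53, SE 0.26, adjusted p = 0.00386). Gata2 fell from 655 ± 140 to 274 ± 40.7 (−1.25, SE 0.18, adjusted p = 0.00134). Of 7 somite and muscle genes Pax3 rose, from 34.4 ± 6.73 to 135 ± 84.0 (1.82, SE 0.36, adjusted p = 0.0099), and Tnnt1 gave −0.98 (SE 0.32, adjusted p = 0.117). In that list 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.8). Of 14 macrophage and blood progenitor genes 1 rose, also adjusted over the list alone (camera adjusted p = 0.101). It was Csf1r, a growth factor receptor of macrophages (0.96, SE 0.20, adjusted p = 0.0126), which no longer passed without KO replicate 2 (0.84). Gfi1b gave 0.65 (SE 0.24, adjusted p = 0.172).

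In the signalling lists, changed genes went both ways. Of 19 genes of the EGF receptor family with its ligands and feedback regulators, 2 rose (Egfr and Dusp6) and 1 fell (Ereg), also adjusted over the list alone (camera adjusted p = 0.159). Dusp6, a phosphatase induced by ERK signalling, gave 0.64 (SE 0.14, adjusted p = 0.0198), and Ereg, the ligand epiregulin, −0.81 (SE 0.21, adjusted p = 0.0412). Among the 4 tested probe sets of Egfr, 3 rose and 1 did not pass (0.92, adjusted p = 0.0785). Of 23 Wnt genes, 3 rose and 3 fell, against 4 and 4 adjusted over the list alone (camera adjusted p = 0.534). The receptors Fzd1 (444 ± 67.1 to 918 ± 109; 1.05, SE 0.14) and Fzd2 (1143 ± 164 to 2066 ± 33.8; 0.86, SE 0.11, adjusted p = 0.000734) rose. Wnt6 fell from 168 ± 96.9 to 44.4 ± 13.8 (−1.80, SE 0.39, adjusted p = 0.0174), and so did Wnt4. Of 23 BMP and TGF beta genes, 5 rose and 4 fell, against 10 and 4 adjusted over the list alone (camera adjusted p = 0.0803). Tgfb2, Bmp4 (412 ± 29.8 to 710 ± 14) and Bmp5 were among those that rose. Inhbb, Inha (359 ± 114 to 121 ± 7.43; −1.51, SE 0.23, adjusted p = 0.00178) and Bmp2 (81.6 ± 19.8 to 23.8 ± 11.1; −1.84, SE 0.35, adjusted p = 0.0079) were among those that fell, the KO mean of Bmp2 lying under the dim limit. Dusp6, Ereg and Wnt6 passed in 2, 1 and 3 of the 6 fits with 1 pool left out.

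Of 18 Notch and Hedgehog genes, 2 rose (Gli3, 0.52, SE 0.11, and Gli2, 0.49, SE 0.12) and 1 fell, also adjusted over the list alone (camera adjusted p = 0.612). Hey1, a Notch target, fell from 900 ± 195 to 505 ± 13.3 (−0.81, SE 0.16, adjusted p = 0.00913). Of 16 planar cell polarity genes, 2 rose (Ror1, 0.78, SE 0.16, and Prickle2, 0.58, SE 0.15), against 3 adjusted over the list alone (camera adjusted p = 0.0621). None of 11 FGF genes passed in either count (camera adjusted p = 0.761). Il17rd lay at −0.55 (SE 0.17, adjusted p = 0.0937) and Fgf10 at 0.41 (SE 0.20, adjusted p = 0.311). Of 13 retinoic acid genes, 1 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.612). Cyp26b1, the enzyme that degrades retinoic acid, rose from 270 ± 16.3 to 798 ± 25.2 (1.56, SE 0.12, adjusted p = 2.23e-05). Rdh10, which makes its precursor, fell from 504 ± 14.1 to 310 ± 25.3 (−0.70, SE 0.13, adjusted p = 0.00776), as did Aldh1a1, Dhrs3 (−0.86, SE 0.19) and Rxrb. Hey1 no longer passed without wild-type replicate 1 (−0.73), and Gli3, Gli2, Ror1, Prickle2 and Dhrs3 passed in 2, 2, 4, 1 and 2 of the 6 fits with 1 pool left out.

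Of 25 Hox genes, 3 rose, against 7 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.504). Hoxa9 went from 2832 ± 220 to 4032 ± 358 (log2 fold change 0.51, SE 0.09, adjusted p = 0.00738), and Hoxa5 rose by 0.54 (SE 0.13) and Hoxd9 by 0.37 (SE 0.09). Of 29 cell cycle genes, Cdk6 rose (0.49, SE 0.12, adjusted p = 0.0281), also adjusted over the list alone (camera adjusted p = 0.551). Aurka gave −0.39 (SE 0.11, adjusted p = 0.0772). Of 19 apoptosis and p53 target genes, Casp8 (0.68, SE 0.14, adjusted p = 0.0153) and Trp53inp1 (0.44, SE 0.11, adjusted p = 0.0429) rose. The counts were 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.359). Of 24 microtubule and centrosome genes, Map1b (748 ± 87.5 to 1215 ± 55.5; 0.71, SE 0.12, adjusted p = 0.00348) and Stmn2 (1.15, SE 0.27) rose and Tubb2b fell (−0.42, SE 0.09). The counts were 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.8). Of 24 immediate early and stress genes, 3 rose and 3 fell, against 3 and 4 adjusted over the list alone (camera adjusted p = 0.8). Among them were Myc (1.08, SE 0.28), Klf6 (0.72, SE 0.14), Jun (−0.76, SE 0.17) and Gadd45b (−0.76, SE 0.19). Of 19 steroidogenesis and cholesterol genes, Hsd3b1 rose (57.8 ± 3.04 to 112 ± 18.2; 0.94, SE 0.22, adjusted p = 0.0258) and Fdx1 fell, also adjusted over the list alone (camera adjusted p = 0.8). Of 22 glycolysis and hypoxia genes, the vasodilator peptide gene Adm fell from 375 ± 122 to 78.3 ± 8.17 (−2.21, SE 0.24, adjusted p = 0.000183). Bnip3 rose by 0.50 (SE 0.12), and the list held 1 higher and 1 lower also adjusted over the list alone (camera adjusted p = 0.229). Without an intensity trend Hoxa9, Fdx1 and Map1b did not pass (adjusted p = 0.113, 0.0798 and 0.0514), and on the deposited values Hoxa9 and Fdx1 did not (0.0904 and 0.284). Hoxa9, Map1b, Fdx1 and Adm passed in all 6 fits with 1 pool left out, Casp8 and Klf6 in 4, Bnip3 in 3, Hoxa5, Stmn2, Tubb2b and Jun in 2, and Hoxd9, Cdk6, Trp53inp1, Myc, Gadd45b and Hsd3b1 in 1.

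Of 27 genes of mitochondrial electron transport, 1 fell and 26 did not pass. It was Cox6c from 8513 ± 588 to 6245 ± 510 (log2 fold change −0.45, SE 0.08, adjusted p = 0.0071), against 2 lower adjusted over the list alone. Cox5a gave −0.29 (SE 0.08, adjusted p = 0.0557), and the list had a median log2 fold change of −0.16 (camera adjusted p = 4.6e-05; adjusted p = 0.407 with an estimated correlation). Of 19 cytosolic ribosomal protein genes, 18 did not pass and 1 fell, Rps24 from 8032 ± 1149 to 6076 ± 527 (−0.40, SE 0.10, adjusted p = 0.0466), also adjusted over the list alone, and Rpl11 gave −0.22 (SE 0.08, adjusted p = 0.157). The list's median was −0.10 (camera adjusted p = 0.00478; adjusted p = 0.628 with an estimated correlation). Its call ended with quantile normalization (adjusted p = 0.629), without an intensity trend (0.0697) and without wild-type replicate 1 (0.0701). Both lists lost their calls on the deposited values without rescaling (adjusted p = 0.105 and 0.294). Rps24 passed in 1 of the 6 fits with 1 pool left out and Cox6c in all 6, although Cox6c did not pass without an intensity trend (adjusted p = 0.146) or on the deposited values (0.484). Without wild-type replicate 3 the called members were 8 for electron transport and 5 for ribosomal proteins, and without any other single pool they were 1 and 0.

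**Figure D4:**
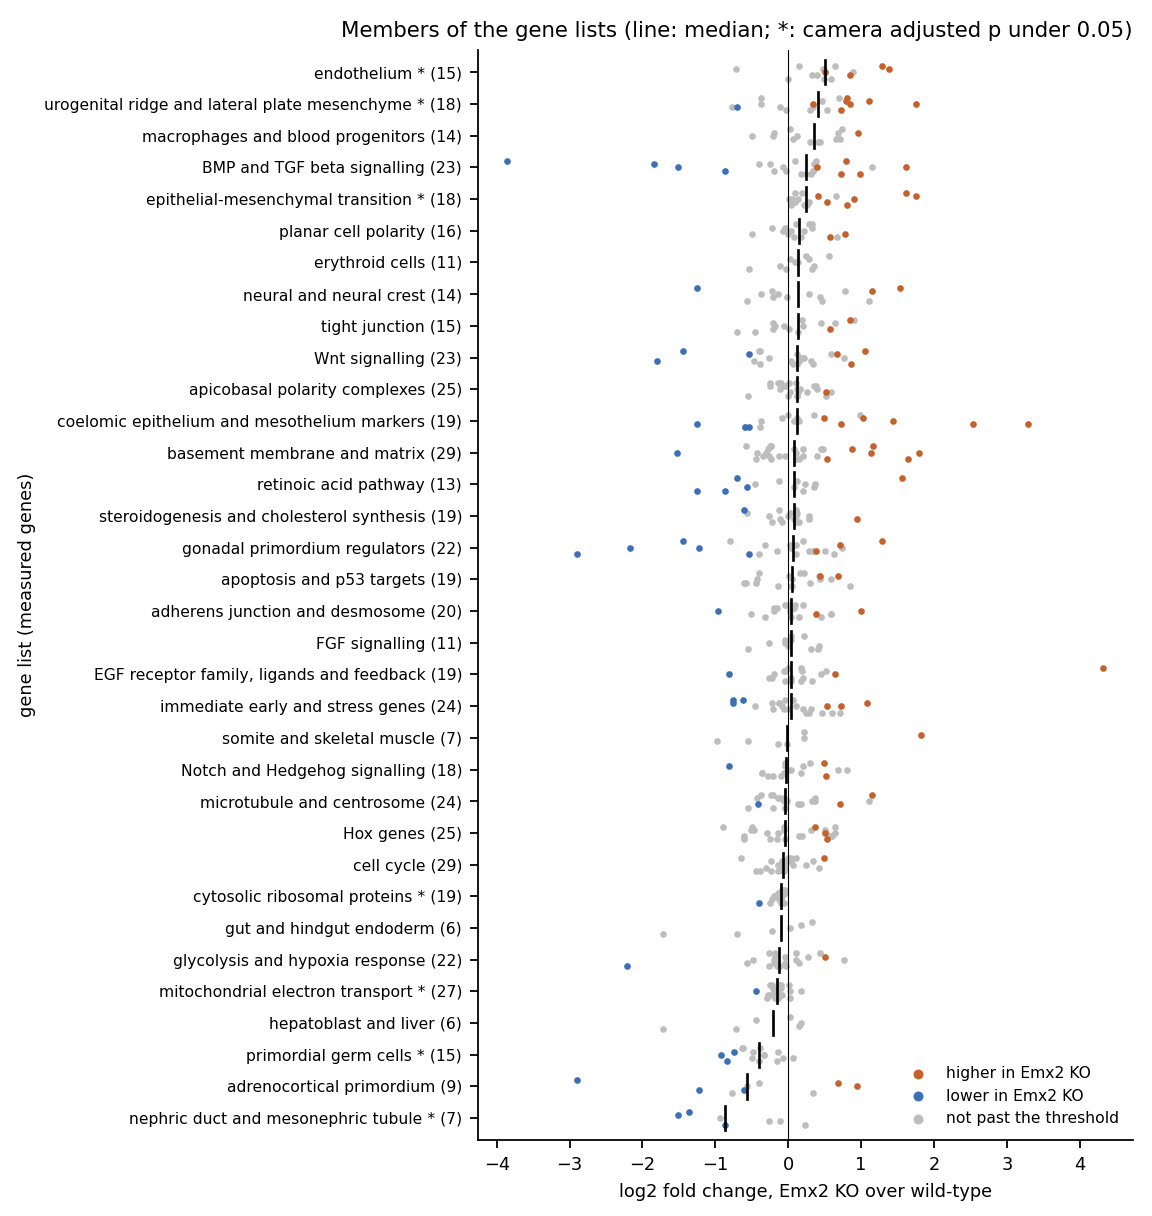
Log2 fold change of Emx2 KO over wild-type for each measured member of the 34 gene lists tested, in orange or blue where the gene was called higher or lower and in grey otherwise, with a black line at the list's median and an asterisk where camera with the preset correlation gave an adjusted p under 0.05. The endothelium list has the highest median (0.51) and the nephric duct list the lowest (−0.87); 7 lists carry an asterisk.

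Calls of named genes ended in several settings. Of 99 named probe sets that passed, 51 also passed in every processing setting in which they were tested other than no filter. Without a filter 16 passed, which were those of Xist, Egfr, Tbx18, Cfap161, Sp6, Myh6, Upk1b, Pkp2, Nectin3, Lama2, Twist1, Cyp26b1, Pdgfrb and Uty, so Cbln1, Inhbb, Nr5a1, Wnt4 and Tgfb2 did not. With filter and floor both left out, a setting added after seeing the data, 24 of the 99 lost their call. Cbln1, Inhbb, Nr5a1, Wnt4 and Tgfb2 were not among those 24. Without an intensity trend 43 lost their call: Stk17b, Gpat3, Adamts18, Aldh1a1, Ezr, Cldn5, Cgnl1, Nectin3, Egfl6, Prrx1, Ereg, Dusp6, Wnt6, Hey1, Gli3, Gli2, Ror1, Prickle2, Stmn2, Map1b, Tubb2b, Cdk6, Casp8, Trp53inp1, Hoxa5, Hoxa9, Hoxd9, Fdx1, Bnip3, Cox6c, Rps24, Myc, Jun, Gadd45b, Pax8, Bmp7, Emcn, Egfl7, Dppa5a, Dppa3, Pax3, Csf1r and Mc2r. On the deposited values 32 did: Ezr, Cgnl1, Nectin3, Ereg, Dusp6, Hey1, Gli3, Gli2, Prickle2, Tubb2b, Cdk6, Casp8, Trp53inp1, Dhrs3, Rdh10, Hoxa5, Hoxa9, Hoxd9, Hsd3b1, Fdx1, Bnip3, Cox6c, Rps24, Jun, Gadd45b, Klf6, Bmp7, Egfl7, Dnd1, Dppa5a, Dppa3 and Mc2r. Quantile normalization ended the calls of Cldn5, Prrx1, Myc and Egfl7, and a common median those of Nectin3, Trp53inp1, Hoxa5, Hoxd9, Rps24 and Egfl7. The replicate block ended those of Nectin3, Ereg, Trp53inp1, Hoxd9, Rps24, Gadd45b, Egfl7 and Dnd1, and the higher floor those of Stk17b and Emcn.

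Over the 34 lists tested, 7 passed camera with a preset correlation of 0.01, 3 of them up and 4 down, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.13. Among these 7, the estimated correlation lay below the preset one for epithelial-mesenchymal transition (−0.013) and nephric duct genes (−0.113). It lay above it for germ cells (0.107), mesenchyme (0.252), endothelium (0.275), electron transport (0.294) and ribosomal proteins (0.45). Coelomic epithelium markers passed with quantile normalization (adjusted p = 0.0411) and with a common median (adjusted p = 0.0487). On the deposited values without rescaling they passed too (adjusted p = 9.16e-05), as did the EGF (adjusted p = 0.0102) and adrenocortical lists (adjusted p = 0.00617). The median, mean and test of a list differed in sign for gonadal primordium regulators (median 0.07, mean −0.21, test down), BMP and TGF beta (0.24, −0.05, up), retinoic acid (0.08, −0.08, down) and Hox genes (−0.05, 0.04, up). It differed also for Notch and Hedgehog (−0.02, 0.05, up), microtubule (−0.04, 0.06, up), somite (−0.02, 0.08, up) and Wnt genes (0.125, −0.002, up). As a sign of RNA quality, the ratio of the 3' to the 5' control probe sets of Gapdh was 3.84 ± 0.39 in wild-type and 3.82 ± 0.29 in KO arrays (SD, n = 3 each; exact two-sided permutation p = 1). That of Actb was 17.0 ± 2.31 and 18.1 ± 3.00 (exact two-sided permutation p = 0.8), where 3 against 3 arrays cannot give a p below 0.1.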

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

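The alternatives without rescaling, without filter and floor together, and without X- and Y-linked genes were chosen only after the result was seen, as were the tests on them; the others were fixed before. Without a filter 45037 were tested and 151 passed, 70.9% of them higher, and 111 of the 1264 were kept. Without filter and floor together 938 passed, 876 of them among the 1264, so most of that loss needed the floor as well as the dim probe sets. Without an intensity trend 541 passed, and at an adjusted p under 0.1 the count was 1939. At an unadjusted p under 0.01 and 2-fold, the count was 357 with the lowest 60% left out, against 666. On deposited values without rescaling 846 passed, 68.4% of them higher, with a median log2 fold change of 0.0979. Other settings gave 1024 to 1407. Beyond that of the floor, the cause was not tested.

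Leaving out 1 pool gave 721 called probe sets (without wild-type replicate 1) to 1687 (without wild-type replicate 3), and the cause was not tested. Of 99 named probe sets that passed, 59 also passed in every such fit in which they were tested and 40 did not, and 0 turned in sign. In every processing setting other than no filter 51 passed, and without a filter 16. Of these named probe sets 43 no longer passed without an intensity trend, 32 on deposited values and 24 without filter and floor. Without wild-type replicate 1, 34 of them no longer passed, and without wild-type replicate 3, 8.

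Of the gene lists, 7 passed, against 0 with an estimated correlation. With the lists of other cell types left out 3 passed, because the mesenchyme, endothelium, nephric duct and germ cell lists were themselves left out. The count was 6 without an intensity trend and 9 both with the lowest 60% left out and with the mean of all probe sets of a gene. With 1 pool left out it was 7 to 10, being 10 without wild-type replicate 3 and without KO replicate 2. The cause of these other changes was not tested. Emx2, at −0.05, ranged from −0.231 to 0.1209 with 1 pool left out and was 0.0242 without KO replicate 2 and 0.047 on deposited values. Lhx9, at 0.02, ranged from −0.0444 to 0.0869, with −0.0266 without wild-type replicate 1, and was −0.0046 with a common median. The Gapdh log2 ratio was −0.005 from 3' to 5' and 0.025 from 3' to middle probe sets. These changes of sign lie around 0, and the cause was not tested.

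With the replicate number as a block 1160 probe sets passed, 1075 of them among the 1264. After each group's mean was taken off every probe set, wild-type and KO arrays of the same number correlated across probe sets, which are not independent replicates, with r of −0.065, 0.04 and −0.051. No sign of a pairing by number was seen, though 3 pairs cannot exclude one, and the unpaired comparison was kept. Signal near background limits dim genes: a group at the floor gives only a lower bound of a fold, and 3964 probe sets lay at the floor in all arrays.

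Of the 10 ways to split the arrays into 3 and 3, 1 gave as many called probe sets as the genotype, 1 as many probe sets at 2-fold and 1 as many lists, which was the genotype itself each time. The real values were 1264, 666 and 7, and the highest others 1, 35 and 5. The other splits, which mix the genotypes, called 4, 5, 3, 0, 4, 1, 5, 5 and 4 lists. Camera with the preset correlation thus also called lists where at most 1 probe set passed, which limits the weight of the 7 lists. With 10 splits a share under 0.05 cannot be reached.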

Other observations

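The test of gene families was chosen only after the result was seen. Grouping the 12315 tested genes by symbol gave 367 families of at least 5, and 3 of them held more called genes than chance gives. The letters of the symbol alone set a family, so Bmp1 and Bmp2k counted as Bmp and Fzd10os as Fzd, whatever they encode. Among 6 Tle genes, co-repressors of transcription, 4 were called where 0.32 were expected (adjusted exact hypergeometric p = 0.0318). Tle1 fell from 1060 ± 343 to 458 ± 81.4 (SD, n = 3 each; log2 fold change −1.18, SE 0.21, adjusted p = 0.00532), Tle6 by 1.19 (SE 0.21) and Tle4 by 0.44 (SE 0.10), whereas Tle3 rose by 0.53 (SE 0.10). Among 18 Sema genes, which encode semaphorin guidance cues, 6 were called where 0.97 were expected (adjusted exact p = 0.0318). Sema3d rose from 108 ± 9.5 to 242 ± 30.8 (1.16, SE 0.18, adjusted p = 0.00203), with Sema5a, Sema6a and Sema4c also higher and Sema3c and Sema6d lower. Sema3c, Sema4c and Sema6d passed narrowly (adjusted p = 0.0448, 0.0459 and 0.0461), and the families were not tested under other settings. Among 7 Bmp genes 4 were called where 0.38 were expected (adjusted exact p = 0.0318), Bmp4 and Bmp5 higher and Bmp2 and Bmp7 lower. The Fzd and Pcdh families, with 4 of 9 genes called and all higher in each, did not pass (adjusted exact p = 0.063), although Pcdh7, a protocadherin, rose from 256 ± 47.8 to 723 ± 112 (1.5, SE 0.17, adjusted p = 0.000207). Nor did Tbx, with 3 of 5 (adjusted exact p = 0.0887), in which Tbx2 fell from 290 ± 96.3 to 73.5 ± 19.4 (−1.95, SE 0.27, adjusted p = 0.00102). Genes of a family are not independent replicates and related probe sequences may respond to each other's transcripts, which the count of 3 families does not rule out.

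The tests of Xist with the Y-linked genes and of autosomal genes were chosen only after the result was seen, while that of genes escaping X inactivation was fixed before. All 4 of Xist, Eif2s3y, Kdm5d and Uty differed as they would if the KO pools held mostly female and the wild-type pools male fetuses. The 9 genes that escape inactivation had a median log2 fold change of 0.296 against 0.039 for other X-linked genes, which met the rule set beforehand. That rule asked for no p-value. A permutation test over genes, used beside it, gave p = 0.135, so whether X-linked dosage differed stays open. Of the other X-linked genes 34 of 406 were called (8.37%) against 621 of 11837 autosomal genes (5.25%; Fisher's exact p = 0.00942), where genes are not independent replicates. Since 0 KO pools reached the wild-type range of Y-linked genes, genotype and sex cannot be told apart for autosomal genes, for which pools matched for sex would be needed.

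The tests of a lower share of the main cell type and of vessels with their blood were chosen only after the result was seen, while that of mesenchyme was fixed before. A lower share of the main cell type in the KO pools would raise the markers of all other cells, but endothelium markers lay 0.952 above germ cell markers in mean log2 fold change. These 2 lists were compared because they had been seen to move apart, so the difference restates the pattern and is no separate test of this explanation. The 5 mesenchyme markers brightest in wild-type had a median of 0.34, above 0 but short of 0.403. A rule fixed beforehand took that level from the median of the mesenchyme markers called higher in these same data (0.805). Markers of the 5 are among those called, so the comparison is partly circular and more mesenchyme cells stay open. Postn (1.10), Pdgfrb (0.85) and Col3a1 (0.34) were called higher, while Col1a2 (0.33, adjusted p = 0.122) and Pdgfra (−0.11, adjusted p = 0.617) did not pass. Erythroid markers had a median of 0.138 against 0.508 for endothelium (permutation p = 0.0294 over genes, which are not independent replicates). That p does not measure the spread between pools, and the erythroid median lies above 0, so more vessels with their blood stay open. Staining of sections for Postn and Tek would show which cells hold these transcripts.

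The tests of an exchanged pool and of the position of the Emx2 probe set were chosen only after the result was seen, while that of the neighbouring genes was fixed before. An exchanged pool would correlate with the other group over all tested probe sets at least as closely as with its own, and 0 of the 6 arrays did, which speaks against an exchange of single pools but not of whole groups; Emx2os lay lower in each pool labelled KO (log2 fold change −2.30), although whether this mutation lowers it is not given in the sources used here. The Emx2 probe set, at −0.046, could lie outside the removed part of the gene, which the sources used here do not let one tell. Of 27 tested neighbours of Emx2, 1 was called, Pnliprp2 (−1.65), which is 3.7% against 5.4% of other genes (one-sided Fisher p = 0.777). So few genes cannot bound the share called, and a regional effect that lowers Emx2os too stays open. Reads across the Emx2 locus from the same mutants would show what transcript remains.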
